A study of Homo sapiens with 2 samples.

How the data were processed

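Total RNA of 2 replicate preparations of MDA-MB-231 cells, transfected at 50% confluency with tagged HNRNPA2B1, was taken before and after immunoprecipitation 72 hours later, per the labels. Both fractions were amplified and labelled with a low-input kit, the co-IP sample with Cy3 and the input with Cy5 on both arrays, per the labels.

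Spot intensities came from the scanner software. The arrays were read with Agilent Feature Extraction 9.5.3.1, per the file headers, and the submitters' processing notes name Agilent Feature Extraction 9. The intensity values used as the main measurement were background-subtracted, detrended and dye-normalized (linear and lowess), with a surrogate value for dim spots, per the file headers. Mean, local background and background-subtracted intensities deposited beside them served the alternatives. The array design carries hg17 coordinates, per the file headers. The log10 ratio in the same deposited files is red over green. The authors also deposited a table of log10 values, 1 per RefSeq accession for 23591 accessions. For all 15540 accessions with 1 spot, the value equalled minus the mean of the log10 ratios of both arrays within 1e-04, so the table holds log10 of co-IP over input, uncentred. Its median is 0, and 15.1% of its values are exactly 0. How the authors combined several probes of an accession is not given in the sources used here.

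From these files, log2 of the Cy3 minus log2 of the Cy5 processed signal was computed per spot, which turns the scanner's own ratio. Control spots and outlier-flagged spots were left out, and spots of one probe were averaged. Each array's log ratios were centred on their median, as fixed beforehand, but the plan did not name the probes to take it over. It was taken over the 38519 probes with an unflagged ratio on both arrays, and 0.12 and 0.19 were removed from replicates 1 and 2. Taking it over the 17084 tested probes instead would have removed -0.04 from both arrays. That alternative was tried only after the ratios had been seen. It moves ratios up by 0.17 and 0.23. No loess followed. A probe was tested when at least 1 channel was well above background on both arrays.

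Genes were named through RefSeq accessions and symbols of a table of assembly GRCh38.p14, used for names only. Of 41000 probes, 23434 matched by accession, 2317 by a current symbol and 1040 by an older one, and 14209 stayed without a symbol. A gene was represented by the tested probe of highest mean log2 signal. limma 3.58.1 in R 4.3.3 fitted an intercept to the ratios of both arrays, with moderated variances (prior degrees of freedom 1.86) and Benjamini-Hochberg adjustment. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, and their medians were placed among 10000 random lists of the same signal decile or the same probe GC.

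The text names HNRNPA2B1, the 12 highest and 12 lowest genes past an adjusted p of 0.05 with the same sign on both arrays and both channels well above background and unsaturated on both arrays, and per list the 3 members of largest absolute ratio that met the same detection and sign conditions. Y-linked genes were not named, and a few items that the rule selects are not reported here. The tests of genes and lists, the lists, the naming rule and most alternatives were fixed before the data were examined. The tests on probe GC and the groups by symbol stem were chosen afterwards. The tests of probe position, of TAG and of histone genes against replication-independent ones were not part of that plan either.

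Alternatives were normexp background correction (offset 50) with and without loess, signals before dye normalization, no centring, loess of processed signals, no filter, a filter on both channels, saturated spots left out, outlier-flagged spots kept, single channels without the array as a block (uncentred), a trended robust variance, the mean over a gene's probes, and each replicate alone. Centring on the tested probes, single channels centred as the main setting, correction of the ratios for probe GC by loess, and random lists of the same probe GC were added later. The GC correction took out the whole trend of the ratio with probe GC across genes. It may therefore also remove differences between RNAs that go with GC, so a call that ended under it is not shown to be a probe effect.

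The procedures were tested on simulated data. With 200 of 9425 simulated genes changed, limma recovered 84.5% of those changed by log2 2 and 25.6% of those changed by log2 1, with 6.45% of its calls false. With 4712 genes changed, the shares were 98.5% and 94.8%, with 2.44% false. With no gene changed it made 0 calls. These simulations drew independent errors from limma's own fitted variances, without centring, dye or GC effects. Their shares of false calls therefore do not describe the error of the calls reported here. Both arrays came from 1 slide and 1 scan, so no batch could be tested.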

Results

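RNA that co-precipitated with HNRNPA2B1, a nuclear RNA-binding protein of the hnRNP family, was compared with the RNA of the same lysate before precipitation (RIP-chip). The cells were MDA-MB-231, a human cell line of triple-negative breast cancer, transfected with a tagged HNRNPA2B1 construct and crosslinked with UV light 72 hours later. Each of 2 two-colour arrays carried the co-IP RNA in Cy3 and its own input RNA in Cy5, so both arrays form 1 group of 2 replicates, and the value of a gene is its log2 ratio of co-IP over input. The arrays held 41000 distinct probes. In the co-IP channel 42.7% and 41.8% of the spots were well above background in replicates 1 and 2, and in the input channel 48.5% and 53.0%. The input channel was on average 12.01 and 14.87 times as bright as the co-IP channel after background subtraction. The number of arrays limits the precision. The labels do not say that the replicates came from separate cultures, so limma's p-values of genes and probes measure only the spread between these samples, which may be technical.

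The first question was which transcripts differed between the co-IP and the input. Both arrays are of the HNRNPA2B1 co-IP, with no control precipitation. A higher ratio therefore cannot be told apart from RNA recovered without the protein. HBB, the beta chain of haemoglobin, had the highest ratio of the named genes, 8.93-fold higher in the co-IP than in the input (log2 3.16 ± 0.17, SD, n = 2). CPEB4, a regulator of cytoplasmic polyadenylation, followed at 4.89-fold (log2 2.29 ± 0.02, SD, n = 2), then EDARADD at 3.99-fold and USP10, a ubiquitin hydrolase, at 3.47-fold. This order and these sizes belong to the main scaling: under normexp with loess HBB was at 1.49 and CPEB4 at 0.90, below TPM4 (1.79), EDARADD (1.78) and HSP90AB1 (1.71). At the other end stood ABTB1 at log2 -4.80 ± 0.09 (SD, n = 2) by the brighter of its 2 probes, but at -0.66 by the other. The H/ACA small nucleolar RNA SNORA70 was at -3.96 and the minor-spliceosome RNA RNU12 at -3.61. In limma's moderated test with Benjamini-Hochberg adjustment, 5515 of 9425 tested genes differed between co-IP and input at 0.05, of which 1853 were higher and 3662 lower. At least 2-fold differences were reached by 354 of the higher and 939 of the lower genes. At the level of probes, 9757 of 17084 passed, 3432 higher and 6325 lower.

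Direction near 0 rested on the centring. The median tested gene lay at log2 -0.20, because the ratios were centred on all probes with an unflagged ratio, dim ones included. Centring on the tested probes, a setting chosen after the ratios were seen, gave 2740 higher and 2398 lower genes (53.3% of the calls higher, against 33.6%). With no centring the split was 2524 to 2664, and with background-subtracted signals before dye normalization it was 2526 to 2734. Loess of the processed signals gave 3024 to 2320, normexp with loess 2485 to 2217, and single channels without the array as a block, which were also uncentred, 2543 to 2541. Centred as the main setting, the single channels gave 1779 to 3381. Normexp without loess put 19 genes higher and 8681 lower. That setting added an offset to raw signals without dye normalization, while the input channel was 12.01 and 14.87 times as bright. Its ratios therefore fall with the brightness of a probe, and its directions, here and below, do not compare with those of the other settings. With no filter on dim probes limma called 0 of 16816 genes. Of the 3662 lower genes, 564 had a co-IP signal that was not well above background on either array, and 54 of the 1853 higher genes had such an input signal, so the ratios of these genes are bounds.

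**Figure D1:**
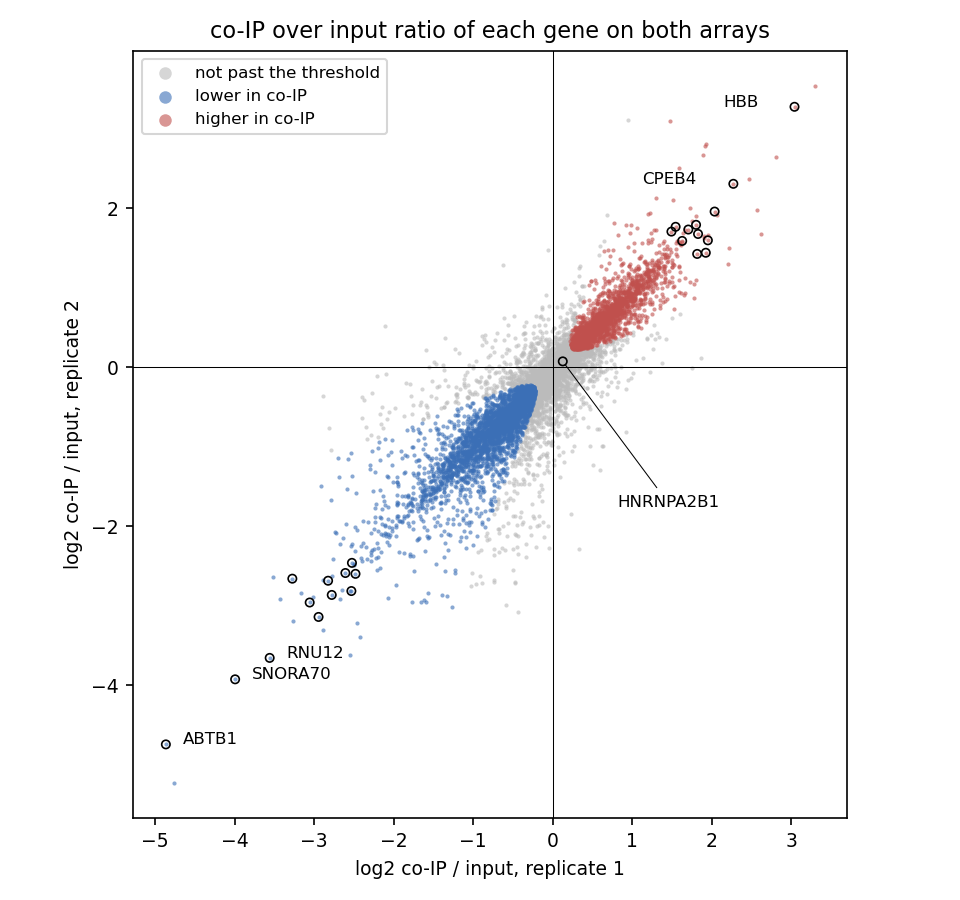
Log2 ratio of co-IP over input of each tested gene in replicate 1 (x axis) and replicate 2 (y axis), coloured by limma's call, with the highest and lowest named genes and HNRNPA2B1 circled. HBB lies at 3.04 and 3.27, ABTB1 at -4.86 and -4.74, and HNRNPA2B1 at 0.13 and 0.07.

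The replicate arrays were compared across genes, which are not independent replicates. Over 9425 genes Pearson's r was 0.884 and Spearman's rho 0.905, and 90.5% of genes had the same sign on both arrays. Among the 7908 genes well above background in both channels on both arrays r was 0.949, and among the other 1517 it was 0.713. The median SD between the arrays was 0.08 on the log2 scale.

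The transcript of HNRNPA2B1 itself was measured by 1 probe, and whether that probe also reads the transfected construct is not known here. Its log2 ratio was 0.10 ± 0.04 (SD, n = 2), 0.13 and 0.07 on the 2 arrays, and it did not pass limma's threshold (adjusted p = 0.247). This outcome changed with the scaling. Centred on the tested probes the ratio was 0.30 with an adjusted p of 0.0294, and without centring it was 0.25 with an adjusted p of 0.0363. Single channels gave an adjusted p of 0.0278 uncentred and 0.316 centred. Over all alternatives with a test the adjusted p ranged from 1.21e-67 to 0.437. The lowest belonged to normexp without loess, which had no dye normalization and turned the ratio to -1.81. The authors' deposited table gives 0.25 for HNRNPA2B1 on the log2 scale, uncentred.

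The naming rule required both channels well above background, so the 54 higher genes without such an input signal on either array could not enter. Within that rule 12 genes had the highest ratios. They comprised HBB, CPEB4, the ectodysplasin receptor adapter EDARADD (log2 2.00 ± 0.06, SD, n = 2), USP10 (1.80), the signal-sequence receptor subunit SSR1 (1.77) and the aminopeptidase LNPEP (1.75). KCTD10 (1.72), the spindle checkpoint kinase BUB1B (1.68), the small GTPase GEM (1.66), the calcium pump ATP2A2 (1.62), the ribosome-assembly factor BMS1 (1.61) and the initiation factor subunit EIF2S1 (1.60) completed them, with adjusted p-values of at most 0.0114 in limma. Mean log2 input signals were lowest for HBB (6.07), SSR1 (6.19), CPEB4 (6.22), BUB1B (6.26), KCTD10 (6.31), GEM (6.67), LNPEP (6.73) and EIF2S1 (7.17). They were higher for ATP2A2 (8.59), USP10 (9.30), BMS1 (9.52) and EDARADD (9.68). The genes with the lower inputs are those that shrank under normexp with loess, given below. The probe of HBB maps to chromosome 11 (5203294 to 5203353, build hg17) and that of EDARADD to chromosome 1 (232973592 to 232973651). A further probe for KCTD10 read -0.09, ATP2A2 had probes at 0.48 and -0.48 and BMS1 had one at -0.05, none of which passed the test, while 2 more of BMS1 were higher, at 0.81 and 0.80. The 12 lowest were ABTB1, SNORA70, RNU12, INKA1 (-3.04), IGSF9 (-3.01), the extracellular adenosine deaminase ADA2 (-2.97), the alpha-globin gene HBA1 (-2.82), the histone genes H4C1 (-2.75), H2BC10 (-2.60) and H2BC14 (-2.54), NKG7 (-2.67) and the anion transporter SLC26A1 (-2.49). Their adjusted p-values in limma were at most 0.00946. A second probe of ABTB1 read -0.66, far above the -4.80 of the brighter one, and both passed. Their mean log2 signals over both channels were 7.92 and 12.69, with 60% GC in each. Whether the brighter probe reads ABTB1 transcripts was not tested. SLC26A1 had a second probe at -1.05, also lower. The authors' deposited table gives -0.51 for ABTB1, -0.17 for HBA1 and -0.90 for SLC26A1 on the log2 scale. The call of ADA2 ended with a trended, robust variance (adjusted p = 0.0840). Under normexp with loess 28 of the 77 named genes other than HNRNPA2B1 moved by over 1.5 times, all of them toward 0. Among the highest these were SSR1 (0.51), BUB1B (0.53), KCTD10 (0.73), GEM (0.75), EIF2S1 (0.75) and LNPEP (0.91) beside HBB and CPEB4. Among the lowest ABTB1 moved to -4.12, SNORA70 to -3.34, RNU12 to -2.69, INKA1 to -2.22, H2BC10 to -1.91, H4C1 to -1.90, HBA1 to -1.72, IGSF9 to -1.59 and NKG7 to -1.51. As the mean over its probes KCTD10 was at 0.81, BMS1 at 0.79, ABTB1 at -2.73 and SLC26A1 at -1.77, and ATP2A2 at 0.54 lost its call (adjusted p = 0.0753). Under normexp without loess the calls of EDARADD, SSR1, LNPEP, KCTD10, BUB1B and GEM ended, at ratios of 0.04, 0.13, 0.13, 0.10, 0.11 and 0.04. The probe behind -4.80 lies on chromosome 3 (128881539 to 128881598, hg17). Probe GC differed between these ends: the 12 highest had a median of 43.3% GC and the 12 lowest 54.2%, against 45% over all tested genes.

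Gene lists fixed before the data were examined were then set against all other tested genes, by camera with a preset correlation of 0.01 over 20 lists of 5 or more tested genes. Its p-values at that setting rest on the spread among genes, taken as nearly independent, and not on the spread between the arrays. 5 lists passed, and none did when the correlation between genes was estimated from the 2 arrays (adjusted p = 0.946 for each list). With only 2 arrays that second test has almost no residual degrees of freedom, so it could hardly pass any list. The olfactory receptor list failed it at an estimated correlation of -0.067 (unadjusted camera p = 0.177, against 0.00106 with the preset one). For the other lists that passed, the estimates lay above the preset 0.01. They were 0.08 for histones, 0.12 for ribosomal proteins, 0.25 for translation factors and 0.27 for splicing factors. The test with an estimated correlation therefore cannot say whether correlation between genes undoes the calls, here or for the lists below. With no filter on dim probes only the histone list passed.

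Replication-dependent histone genes, whose mRNAs mostly end in a stem-loop without a poly(A) tail, fell. Of 58 tested members 43 were lower in the co-IP, 4 higher and 11 did not pass (44 lower and 7 higher adjusted over the list alone). Their median was -0.83, with -0.81 and -0.92 on the 2 arrays, and their mean lay 0.79 below that of the other genes (list minus others -0.79, camera adjusted p = 0.00106, and adjusted p = 0.946 with an estimated correlation). H4C1 (6.75-fold lower), H2BC10 (6.05-fold lower) and H2BC14 (5.81-fold lower) led the list. The list includes 1 gene that also stands on the list of polyadenylated, replication-independent histones. Histone genes are near-identical copies, so their probes may share targets. The histone probes had a median GC of 54.2%. After correction for probe GC, an alternative added after the data were seen, the shift was -0.55 with a camera adjusted p of 0.0715. The counts were then 10 higher and 35 lower.

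Cytosolic ribosomal protein genes stood higher than other genes (list minus others 0.28, camera adjusted p = 0.00837, adjusted p = 0.946 with an estimated correlation). Of 81 tested, 27 were higher, 13 lower and 41 did not pass (26 higher and 11 lower adjusted over the list alone), with a median of 0.07. Lower members included RPL18 at -0.79 and RPS13 at -0.72, although 2 further probes of RPS13 read -0.09 and -0.04 without passing and the authors' deposited table gives 0.12 for it. Its call ended with loess of processed signals (-0.24, adjusted p = 0.156). Centred on the tested probes, 38 were higher and 9 lower. The list's direction turned in 2 settings, to -0.45 with background-subtracted signals before dye normalization and to -1.39 under normexp without loess. Its call ended with the mean over a gene's probes (adjusted p = 0.0626).

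Translation initiation and elongation factors also stood higher (list minus others 0.36, camera adjusted p = 0.00926, adjusted p = 0.946 with an estimated correlation), with 21 higher, 11 lower and 26 not past the threshold of 58 tested (20 higher and 11 lower adjusted over the list alone). EIF2S1 (log2 1.60) and the helicase EIF4A1 (1.47) were among the higher members, and the scaffold EIF4G1 (-1.65) was lower. The probes of EIF4A1 did not read alike: the other 3 stood at -0.53, which was called lower, and at -0.29 and -0.25, which did not pass. Their mean with the first was 0.10 (adjusted p = 0.301), and the authors' deposited table gives -0.10. The hnRNP and SR splicing factors had a list minus others of 0.31 (camera adjusted p = 0.0467, adjusted p = 0.946 with an estimated correlation). Of 43 tested, 15 were higher, 11 lower and 17 did not pass (16 higher and 12 lower adjusted over the list alone). SCAF4 (1.14), HNRNPK (1.09) and HNRNPLL (1.02) were higher, each about 2-fold, while a second probe of HNRNPK was called lower, at -0.27 (adjusted p = 0.0494). Both lists turned under normexp without loess, to -0.28 for the translation factors and -0.10 for the splicing factors, and both calls ended after correction for probe GC (adjusted p = 0.108 and 0.0715). Centred on the tested probes, 31 translation factors were higher and 5 lower, and 22 splicing factors higher and 5 lower. The splicing factors' call also ended where both channels had to be well above background (adjusted p = 0.0940) and in single channels centred as the main setting (adjusted p = 0.0607).

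Olfactory receptor genes, which are silent in most cells outside the nose, were lower (list minus others -1.21, camera adjusted p = 0.00837, adjusted p = 0.946 with an estimated correlation). Of 114 on the array 15 were tested, and 12 were lower, 0 higher and 3 not past the threshold (15 lower adjusted over the list alone). OR10A5 was at -1.45, OR5H1 at -1.35 and OR2H1 at -1.18. The probes of OR10A5 and OR2H1 had mean log2 input signals of 15.45 and 16.11, above the 13.30 of GAPDH, while that of OR5H1 had 8.03. Both were bright in the co-IP too (14.15 and 15.08). Whether such bright probes read olfactory receptor transcripts was not tested. OR5H1 moved to -0.34 under normexp with loess, and the authors' deposited table gives 0.10 for OR2H1. Only 6 of the 15 had both channels well above background on both arrays, and their median was -1.11. The filter passes probes that are bright in the input alone, so it can select low ratios. With no filter the shift was -0.21 (adjusted p = 0.903) and the median -0.004. Under normexp without loess the call ended, with a shift of -0.18.

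**Figure D2:**
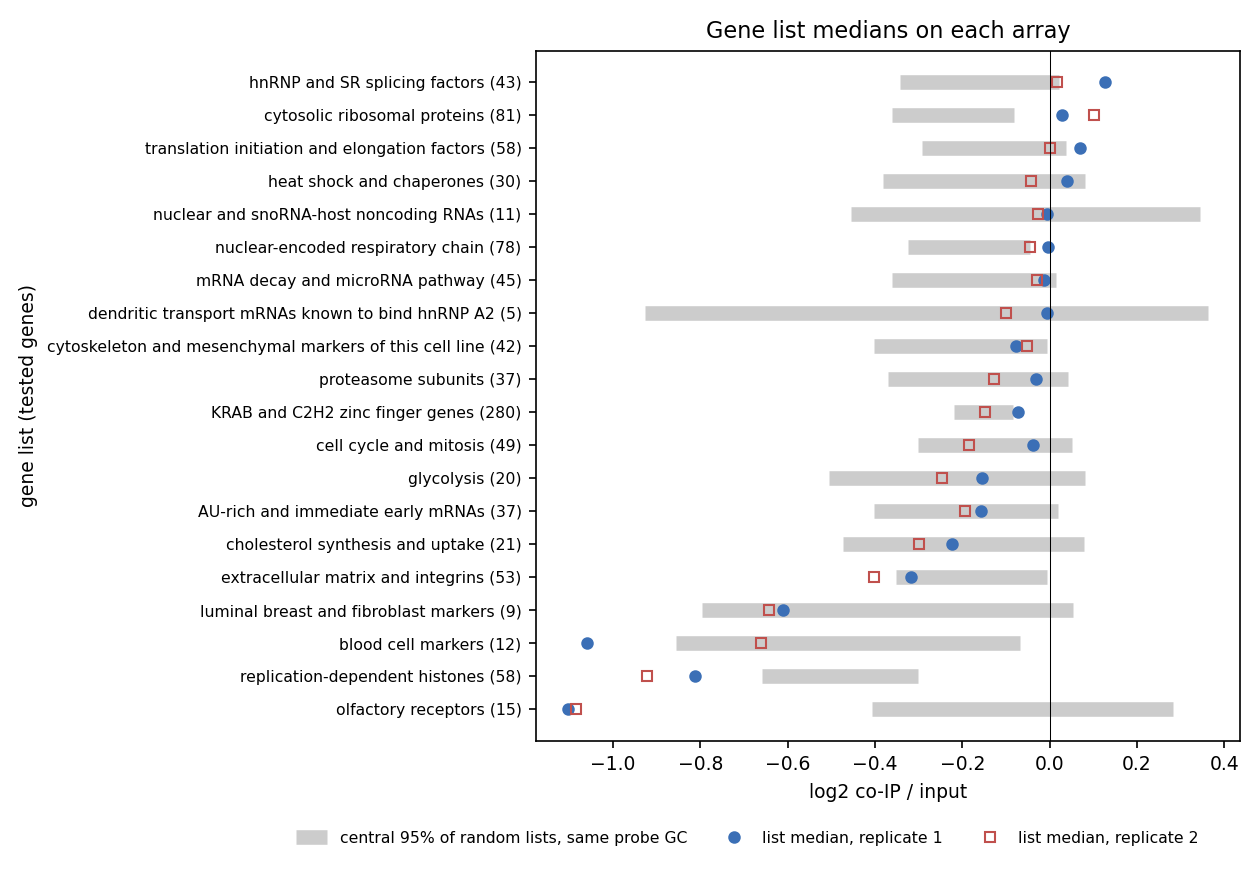
Median log2 ratio of co-IP over input of each gene list on replicate 1 (filled circles) and replicate 2 (open squares), with the number of tested genes; grey bars span the central 95% of medians, averaged over both arrays, of 10000 random lists of the same size and probe GC. Replication-dependent histones lie at -0.81 and -0.92, below their grey bar of -0.66 to -0.30.

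The other 15 lists did not pass, and for most of them the counts of higher and lower members depended on the centring. Members of the respiratory chain went both ways, 19 higher and 27 lower of 78 (adjusted over the list alone, likewise 19 and 27, but 35 and 19 centred on the tested probes and 32 and 20 without centring). NDUFS8 (-1.60), NDUFA3 (-1.21) and COX6A2 (-1.02), all lower, had the largest absolute ratios under the naming rule. Proteasome subunits had 9 higher and 9 lower of 37 (8 and 7 adjusted over the list alone; 15 and 4 centred on the tested probes), among them PSMD5 at -1.51 with a second probe at 0.28 that did not pass, PSMC5 at 1.09 and PSMB9 at -1.07. The proteasome list passed under normexp with loess (camera adjusted p = 0.0274, against 0.316) and with loess of processed signals (adjusted p = 0.0485). Of 280 KRAB and C2H2 zinc finger genes 75 were higher and 94 lower (76 and 95 adjusted over the list alone), against 104 and 68 centred on the tested probes and 99 and 71 without centring, and ZNF331 (-2.10), ZNF670 (-1.78) and ZNF721 (-1.63) were lowest among those named. Under normexp with loess these 3 were at -0.78, -0.58 and -0.83, and the authors' deposited table gives 0.31 for ZNF331. Cell cycle genes counted 14 higher and 18 lower of 49 (14 and 19 adjusted over the list alone), against 18 and 6 centred on the tested probes and 17 and 8 without centring, with CDK1 at 1.16 and MCM4 at 1.11 beside BUB1B. Glycolysis genes counted 4 higher and 9 lower of 20 (the same 4 and 9 adjusted over the list alone, 6 and 6 centred on the tested probes), from GAPDH at 1.17 to PFKFB3 at -1.10 and PFKL at -1.62. A second probe of PFKFB3 was higher, at 0.48, and the authors' deposited table gives 0.65. Heat shock and chaperone genes counted 9 higher and 9 lower of 30 (9 and 10 adjusted over the list alone, 15 and 6 centred on the tested probes), led by HSP90AB1 (1.44), PDIA3 (0.95) and BAG3 (0.93). A second probe of BAG3 was lower, at -0.53, and the mean of both, 0.20, did not pass (adjusted p = 0.0825). The mRNA decay and microRNA pathway counted 10 higher and 9 lower of 45 (9 and 7 adjusted over the list alone), with UPF2 at 1.12, XRN1 at -0.86 and SMG6 at 0.83. The authors' deposited table gives 1.38 for XRN1, and normexp with loess -0.20. Centred on the tested probes this list counted 17 and 5 and passed (camera adjusted p = 0.0471, against 0.242). It also passed with signals before dye normalization (adjusted p = 0.0348) and with loess of processed signals (adjusted p = 0.0485).

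Cytoskeletal and mesenchymal genes counted 7 higher and 12 lower of 42 (6 and 9 adjusted over the list alone), against 16 and 7 centred on the tested probes and 15 and 7 without centring, with TPM4 at 1.40, ACTN4 at -1.31 and PFN1 at -1.22. Of 53 extracellular matrix and integrin genes 9 were higher and 30 lower (the same 9 and 30 adjusted over the list alone, 12 and 21 centred on the tested probes), with COL10A1 at -1.75, COL27A1 at -1.33 (0.06 by a second probe, not past) and COL8A1 at -1.25. AU-rich and immediate early mRNAs counted 9 higher and 13 lower of 37 (likewise 9 and 13 adjusted over the list alone, 12 and 9 centred on the tested probes), with IER5 at -1.34 (-0.20 by a second probe, not past), AREG at -0.98 and DUSP6 at -0.97. Cholesterol genes counted 1 higher and 11 lower of 21 (1 and 10 adjusted over the list alone, 4 and 5 centred on the tested probes), with PMVK at -0.97, DHCR7 at -0.78 and MVK at -0.51. Nuclear and snoRNA-host noncoding RNAs counted 2 higher and 4 lower of 11 (also 2 and 4 adjusted over the list alone, 5 and 2 centred on the tested probes), with MEG3 at -1.27, SNHG12 at -0.85 and MALAT1 at 0.71, and 2 of the 4 probes of MALAT1 were lower. Of the 12 dendritic transport mRNAs described as bound by hnRNP A2, 5 were tested, with 2 higher and 2 lower (the same adjusted over the list alone): ARHGDIA was at -0.66, BDNF at 0.64 and NRGN at -0.43. After correction for probe GC the counts were 1 and 0, and the calls of ARHGDIA (-0.15, adjusted p = 0.221) and NRGN (-0.17, adjusted p = 0.0992) ended. NRGN also lost its call under normexp with loess (-0.10, adjusted p = 0.141) and with loess of processed signals (-0.19, adjusted p = 0.0957), and BDNF turned to -0.37 under normexp without loess. Blood cell markers counted 1 higher and 8 lower of 12 (the same adjusted over the list alone; camera adjusted p = 0.160), with CD4 at -1.14 beside HBB and HBA1. With loess of processed signals this list passed (adjusted p = 0.0485). The CD4 probe had a mean log2 input signal of 16.58, above the 13.30 of GAPDH, and whether it reads CD4 transcripts was not tested. Luminal breast and fibroblast markers counted 0 higher and 6 lower of 9 (again the same adjusted over the list alone; camera adjusted p = 0.308), with THY1 at -1.16, SPDEF at -1.06 and EPCAM at -0.68. With no filter the medians of these 2 lists were -0.14 and -0.09, against -0.83 and -0.66. Under normexp without loess 5 further lists passed: the respiratory chain (adjusted p = 6.84e-08), cytoskeleton (0.000485), glycolysis (0.00691) and chaperones (0.0180) with shifts below 0, and zinc finger genes (0.0317) with a shift of 0.25. Further moves of over 1.5 times were under normexp with loess to -0.40 for ACTN4, -0.67 for COL10A1, -0.98 for EIF4G1, -0.37 for PSMB9, -0.70 for PSMD5 and -0.26 for SPDEF. As means over the probes they were to 0.41 for HNRNPK, 0.83 for HSP90AB1, -0.63 for COL27A1, -0.31 for PFKFB3, -0.61 for PSMD5 and, turned, -0.10 for MALAT1. The authors' deposited table gives -0.04 for IER5 and -0.08 for MEG3. Calls also ended for MEG3 in single channels (adjusted p = 0.128 uncentred, 0.0732 centred), for AREG with signals before dye normalization (adjusted p = 0.0502) and for MVK after correction for probe GC (adjusted p = 0.0761). The array held 0 genes of the mitochondrially encoded list.

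Ratios fell with the GC content of the probe above 45%. The median log2 ratio was -0.06 over the 3461 genes with probes above 40% and up to 45% GC, -0.46 at 50 to 55%, -0.75 at 55 to 60%, and -1.11 over 149 genes above 70%. It was -0.37 over the 135 genes at or below 30%. Of the genes above 70% GC, 87.2% were called lower.

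**Figure D3:**
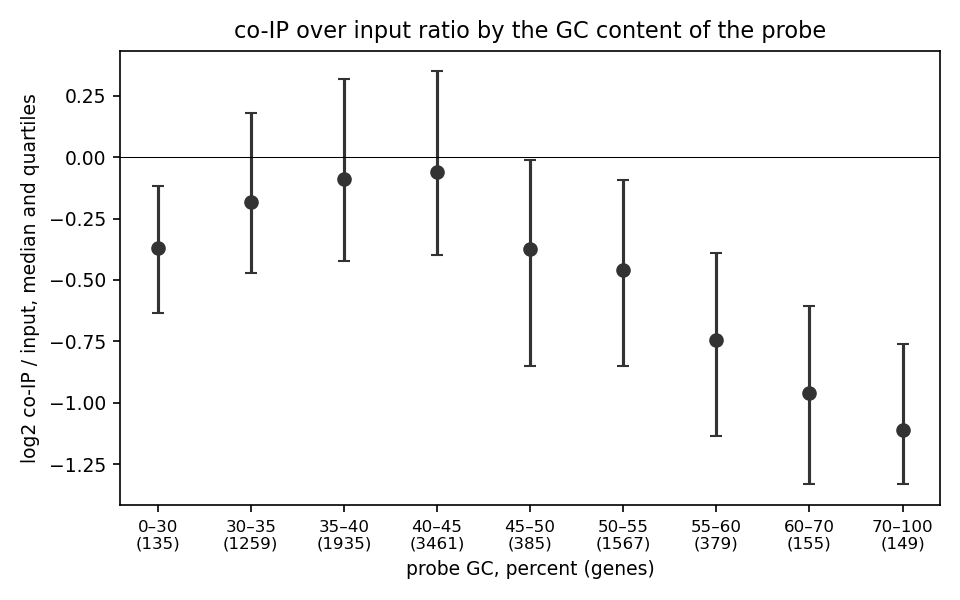
Median log2 ratio of co-IP over input (points) with the lower and upper quartiles (bars), by the GC percentage of the gene's probe, with the number of genes per bin. The median is highest, -0.06, at 40 to 45% GC and falls to -1.11 above 70%.

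Different probes of a gene often disagreed. Of 2416 genes with several tested probes, 52.9% had all probes on one side of 0. Among the 944 genes with at least 2 called probes, 367 had calls in both directions. The dyes were not swapped, so the dye is confounded with the fraction in every ratio above.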

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

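Centring on the tested probes, centred single channels, correction for probe GC and random lists of the same probe GC were chosen after the data were seen; the other settings were planned. Surrogate values stood in 33.1% and 32.6% of the co-IP spots and 31.2% and 27.9% of the input spots. Normexp without loess had no dye normalization, so its directions carry the brighter input channel and do not compare with the others. The cause of the other changes below was not tested, except where fewer or more genes entered the test.

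HNRNPA2B1 (0.10, adjusted p = 0.247) passed the threshold in 6 settings with the same direction: 0.22 under normexp with loess, 0.20 with signals before dye normalization, 0.25 without centring, 0.34 with loess of processed signals, 0.30 centred on the tested probes and 0.25 without the replicate block. The last of these was also uncentred, and single channels centred as the main setting gave 0.10 (adjusted p = 0.316). It turned to -1.81 under normexp without loess. Over all tested alternatives its adjusted p ran from 1.21e-67 to 0.437. The authors' deposited table gives 0.25. Either array alone gave 0.07 to 0.13, with no test possible on 1 array. The array has 1 probe for it, so no other probe could be tried, and the authors' deposited table, with 1 mean per accession, allows no counts or agreement between arrays.

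The count of genes stayed within 1.5 times of 5515 except for 8700 under normexp without loess (19 higher, 8681 lower), 0 with no filter (0 higher, 0 lower, and 0 probes), and 1293 at 2-fold or more (354 higher, 939 lower). Probes likewise gave 15467 under normexp without loess (50 higher, 15417 lower). Lower genes were 2217 under normexp with loess (3693 probes), 2320 with loess of processed signals (4126 probes, beside 3024 higher genes and 5328 higher probes) and 2398 centred on the tested probes (4182 probes). Of the 5138 genes called with that centring, 4239 were also called in the main setting. No paired analysis beyond the array ratio was possible because each array already pairs both fractions; without the replicate block 5084 genes passed uncentred, against 5188 by ratios without centring, and 5160 passed centred.

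Pearson's r between the arrays was 0.930 under normexp with loess, 0.983 under normexp without it, 0.887 with loess of processed signals, 0.680 with no filter, 0.948 with both channels above background, 0.900 with outlier-flagged spots kept and 0.869 after GC correction.

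The 5 list calls became 4 in centred single channels, with both channels above background and with the mean over probes, 6 under normexp with loess, with signals before dye normalization, centred on the tested probes and against random lists of the same probe GC, and 7 under normexp without loess. They became 8 with loess of processed signals, 8 against random lists of the same signal, 2 after GC correction and 1 with no filter. With an estimated correlation 0 passed, but 2 arrays leave that test almost no power to pass a list. Under normexp without loess the list shifts turned to -0.10 (hnRNP and SR), -1.39 (ribosomal), -0.28 (translation factors), -0.74 (respiratory chain), -0.30 (proteasome), 0.021 (matrix), -0.12 (AU-rich), -0.57 (noncoding RNAs), -0.11 (cell cycle), -0.66 (glycolysis), -0.49 (chaperones), -0.61 (cytoskeleton), 0.042 (blood) and 0.021 (luminal). Signals before dye normalization turned the ribosomal list to -0.45, the respiratory chain to -0.037, glycolysis to -0.14 and the cytoskeleton to -0.021. With no filter, AU-rich mRNAs turned to -0.023, noncoding RNAs to -0.12 and glycolysis to -0.036. With both channels above background noncoding RNAs turned to -0.014 and glycolysis to -0.045. Cholesterol genes turned to 0.063 with outlier-flagged spots kept, and noncoding RNAs to -0.057 after GC correction and -0.080 with the mean over probes.

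Of 1382 values of the 77 named genes besides HNRNPA2B1, 1204 did not change their call or moved by under 1 SD, 96 lost significance (77 of them with no filter), 55 moved and 27 turned. Of all these values 115 differed from the main one by over 1.5 times, and 74 of the 115 are among those 1204. By setting these were 61 genes under normexp without loess, 28 under normexp with loess, 13 as the mean over probes, 11 in the authors' deposited table, and 1 each with signals before dye normalization and after GC correction. Under normexp without loess USP10 turned to -0.095, ATP2A2 to -0.14, BMS1 to -0.25, EIF2S1 to -0.010, SCAF4 to -0.11, HNRNPK to -0.79, HNRNPLL to -0.56, EIF4A1 to -0.54, PSMC5 to -0.88, MALAT1 to -1.45, CDK1 to -0.56, MCM4 to -0.30, GAPDH to -0.96, HSP90AB1 to -0.62, PDIA3 to -0.98, BAG3 to -0.61, UPF2 to -0.38, SMG6 to -0.34, TPM4 to -0.75 and BDNF to -0.37. MALAT1 turned to -0.10 as the mean over its probes. In the authors' deposited table EIF4A1 stands at -0.10, OR2H1 at 0.10, PFKFB3 at 0.65, RPS13 at 0.12, XRN1 at 1.38 and ZNF331 at 0.31.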

Other observations

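Gene classes outside the fixed lists were tabulated after the data were seen. All 3 tested small nucleolar RNA genes were called lower, with a median log2 ratio of -1.99, and so was the 1 tested small nuclear RNA, RNU12, at -3.61; SNORA70 and RNU12 are already among the 12 lowest genes of the report. Of 67 tested lncRNA genes 10 were higher and 30 lower, against 1823 and 3587 of the 9251 protein-coding genes. No test compared these shares. Among 112 groups of at least 8 tested genes that share a symbol stem, formed after the data were seen, limma's camera called 0 after adjustment. The annexins came nearest (camera adjusted p = 0.128), with 7 of 10 members higher, 1 lower and a median of 0.43.

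The fall of the ratio with probe GC was seen before its tests were chosen. Among 1262 genes with several probes of at least 40% GC, the log2 ratio changed by -0.21 per 10 points of probe GC within genes (95% interval -0.26 to -0.16), while between genes it changed by -0.50. A GC effect of the probe itself, from hybridisation, labelling or dye, may therefore account for part of the trend; the interval spans the mark of -0.25 set for it, so how much stays open. The slope between genes was steeper than that within by -0.29 (-0.35 to -0.22), as a difference between RNAs beyond the probe's own GC would need. The slope within genes was not adjusted for probe position. Over 2355 genes the most 3' probe minus the most 5' one had a median of -3.33 points of GC and of -0.18 in log2 ratio. Position may thus flatten the slope within genes, so the steeper slope between genes does not decide for a difference between RNAs. A co-IP signal near background was argued against as the whole account, since the slope between genes was -0.46 (-0.51 to -0.41) among probes well above background in both channels. The dye is confounded with the fraction, so a preference of the protein was not tested.

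Replication-dependent histone genes lay at percentile 0.01 of 10000 random lists of the same probe GC. Random lists and the rank-sum tests below take genes as independent, while histone probes may share targets, so these values may be too extreme. Within that limit the percentile argues against probe GC as the whole account. The camera call, however, ended after GC correction at an unchanged direction (-0.79 before, -0.55 after, adjusted p = 0.0715). Among the 56 such genes well above background in both channels the median of -0.83 lay at percentile 0 of random lists, which argues against a signal near background. The missing poly(A) tail remains a candidate explanation: 9 polyadenylated, replication-independent histone genes had a median of -0.15, against -0.85 in the 57 replication-dependent genes that are not also on that list, 0.71 higher (exact two-sided rank-sum p = 0.00641). Their probes are poorer in GC (43.3% against 55% in those 57), and after GC correction the difference was 0.21 (exact p = 0.132), so poly(A) and probe GC cannot be told apart here. The replication-independent list shares 1 gene with the 58 of the report. Without it the difference was 0.72 over 8 genes (exact p = 0.00414), and 0.24 after GC correction (exact p = 0.0960). These rank-sum tests were not part of the plan fixed before the data were examined.

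Probes of one gene differed by a median of 0.56 between its most 5' and most 3' probe. Loss of sequence away from the 3' end of the co-IP RNA would raise the most 3' probe, but it was the higher one in only 40.6% of 2355 genes (exact binomial 95% interval 38.6 to 42.7%). Whether UAG, a motif described for this protein, marks higher ratios was tested at equal base composition: probes with TAG differed by -0.018 (95% interval -0.046 to 0.009), and 4 of the 5 other orders of the same letters had a higher coefficient, so the probes themselves gave no sign of it. Sites outside the probes were not searched.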
